A study of Drosophila melanogaster with 3 samples.

How the data were processed

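Chromatin immunoprecipitation sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos collected 0 to 24 h after egg laying. They came from transgenic flies that express an Optix-eGFP fusion, per the labels. The immunoprecipitation used an antibody against GFP, so the measured sites are those recovered with the tagged protein. Per the labels, the chromatin was sheared by sonication, fragments ran from 200 to 800 bp, and there were 3 biological replicates of the same group. The labels name a possible control experiment, which was not used here, so no comparison was made with another strain or with input.

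For each replicate, the authors deposited a list of peaks that passed an irreproducible discovery rate (IDR) limit and a longer ranked list of candidates. A further 4 pairs of such lists stand for the series as a whole, and 1 of them is called conservative. All 3 libraries are given as the source of each series-level list, per the labels' file list, but how they were pooled or compared is not given in the sources used here, and these lists were printed as the authors' values with no SD. The genome build was dm6, per the labels. The aligner and the peak caller are not given in the sources used here. The score column deposited by the authors is a scaled IDR, and the lowest score in every thresholded list was 830. The ranked lists deposited by the authors also hold the −log10 of the global IDR, and all listed peaks had a value of at least 2, which is an IDR of at most 0.01. The signal column deposited by the authors is a peak's own strength. It was used to describe, rank or filter peaks within a list and, since it was not scaled between lists, was compared between replicates by rank correlation. Read depth is unknown from these files, so intervals cover counting of peaks only.

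Listed peaks were compared with the ranked candidates that missed the limit. Candidates that passed it but were missing from the matching thresholded list were counted on neither side. Peaks were called shared when the overlap reached 50% of the shorter peak. Sharing was tested with 1000 circular shifts of a list within chromosome arms, 2-sided, adjusted over the 6 ordered pairs. Summits were assigned by priority to promoter (within 500 bp of a transcription start), 5' UTR, 3' UTR, coding exon, noncoding exon, intron and intergenic sequence, from the Ensembl annotation on dm6 coordinates. Location classes and chromosome arms were tested with 2-sided Fisher's exact tests. Benjamini-Hochberg adjustment was used throughout, over each family of tests, with a threshold of 0.05. Odds ratios carry 95% limits by Woolf's logit method, with a continuity correction for motifs, and ratios within strata are Mantel-Haenszel ratios. The exact stratified test was conditional on the margins of each stratum, 2-sided, adjusted over 8 tests, and was tested on simulated data. Shares carry 95% Wilson intervals. Neighbouring peaks are not independent replicates, so the direction in the 3 replicates is given beside such tests.

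Motifs were searched as exact matches on either strand within 50 bp of the summit in the Release 6 sequence, for 16 fixed sites and for all sequences of 6 bases. The background was failing candidates of the same GC decile and location class. The plan allowed up to 5 per peak, but the number was kept equal over all combinations of decile and class, and the scarcest of them allowed 1 per peak. For 21 fixed gene lists, the share of genes with a conservative-list summit in the gene body extended by 2 kb was compared with 10000 random lists matched on decile of gene length, as a 2-sided permutation test. Of the listed symbols, 5 were found under a current name and 1 was not found. Conservative-list summits fell in 2888 of 13986 extended protein-coding genes, or 20.6%.

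The genes named in the text followed a rule fixed before the data were examined, as were the fixed motifs, the gene lists and the planned tests. Some further tests and alternatives were chosen after seeing the data. The genes under the rule are Optix, the gene with the nearest transcription start to each of the 25 strongest conservative-list peaks found in all 3 replicates, and list members by highest signal. The signal given for a list member is that of its strongest peak in the extended gene, which can lie at the start of a neighbouring gene. Up to 5 members were taken from a list with an adjusted p under 0.05 and up to 2 from the others. A gene that the rule names is not reported here. Genes outside the rule are marked as chosen after their values were seen.

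The overlap, location, motif and gene list procedures were tested on simulated data. Among 1000 simulated peaks with 40% shared, 40.3% were recovered. A promoter odds ratio of 3 among 2000 peaks came out as 3.13. A TGATAC odds ratio of 2 among 2000 peaks came out as 1.73. Of 21 simulated gene lists, the 1 planted list was called and 0 of the others were. Alternatives covered the overlap rule, the promoter width, the background, the peak list, the IDR limit, the gene extension and each replicate left out. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The fixed random seed was 20240.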

Results

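Binding of the homeodomain protein Optix, a Six-family regulator of eye and forebrain development, was profiled in 3 replicates of whole embryos aged 0 to 24 h, to map where the tagged protein is found on chromatin. The thresholded lists held 1584 peaks in replicate 1, 1448 in replicate 2 and 2188 in replicate 3, from 108037, 109892 and 112045 ranked candidates. The conservative series-level list held 2476 peaks, and the longest series-level list held 3523. There was 1 group, so no comparison between groups was made.

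The tagged gene lay in a dense group of peaks. Optix is at 2R:8031283-8042529 on the plus strand (FBgn0025360, dm6), and the conservative list held 9 peaks within 20 kb of it. The strongest was at 2R:8060838-8061185, in an intron with the nearest start at CG12769, with a signal of 1236 and rank 20 in the list. The next was intergenic at 2R:8014306-8014500, with a signal of 636. These peaks were in all 3 replicates. The peak at the Optix promoter itself, 2R:8030823-8031172, had a signal of 135.9 and was overlapped in replicate 1 alone of the replicate lists.

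Peak density within 20 kb of Optix was 9.62 times that of the rest of the main arms in the conservative list. Over the replicates it was 10.9 ± 5.35 times (SD, n = 3), with 13.3, 14.7 and 4.81 times from 8, 8 and 4 peaks. As many peaks were found in 6 of 2609 windows of that size in the conservative list, and in 3, 0 and 97 of them in replicates 1, 2 and 3. Ranked candidates were 1.43 times as dense there as elsewhere. In a comparison chosen after seeing the data, failing candidates there had median signals 1.43, 1.27 and 1.82 times that of failing candidates on the main arms in replicates 1, 2 and 3. Within 10 kb of Optix the replicates differed, with 3, 5 and 0 peaks.

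**Figure D1:**
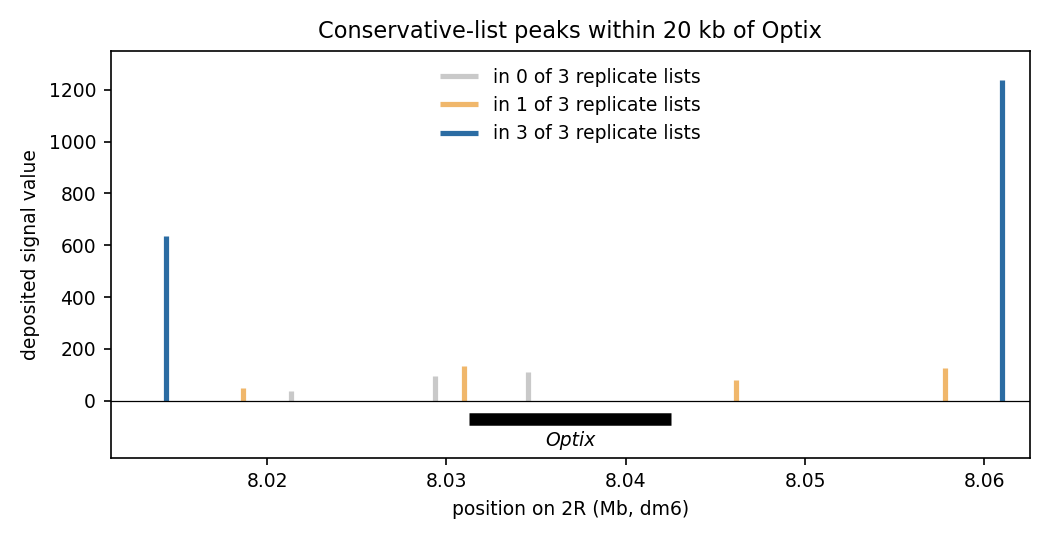
Conservative-list peaks within 20 kb of Optix, drawn at their summits on 2R (Mb, dm6) with the deposited signal value as height and colour for the number of replicate lists that overlap each. The peaks found in all 3 replicates, with signals of 636 and 1236, lie on either side of the gene, and the other 7 have signals from 39.5 to 135.9.

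Strong peaks recurred in the thresholded lists of other replicates and weak ones often did not. A peak whose counterpart missed the limit in the other replicate counted as not shared. The lengths of the lists also limit these shares, most of all for replicate 3, which has the longest list. The replicates held 1740 ± 394 peaks (SD, n = 3). Replicate 2 had 83.3% of its peaks in replicate 3, the highest share, and replicate 3 had 52.9% of its peaks in replicate 1, the lowest. Of the 500 strongest peaks of each replicate, between 95.6% and 99% were found in another. Of the 500 weakest, between 16.6% and 61.8% were. In the conservative list, 919 of 2476 peaks were overlapped in all 3 replicates (37.1%, 95% Wilson interval 35.2 to 39.0%), with a median signal of 285. The 479 peaks overlapped in 0 replicates had a median signal of 90.3.

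Shifted lists overlapped by at most 1.26%, against a lowest observed share of 52.9%. Each of the 6 ordered shares had a permutation p of 0.002, the smallest that 1000 shifts can give in a 2-sided test, and the same value after adjustment. Across the 919 shared peaks, Spearman correlations of signal were 0.771 between replicates 1 and 2, 0.759 between 1 and 3, and 0.864 between 2 and 3. These are across peaks, which are not independent replicates.

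**Figure D2:**
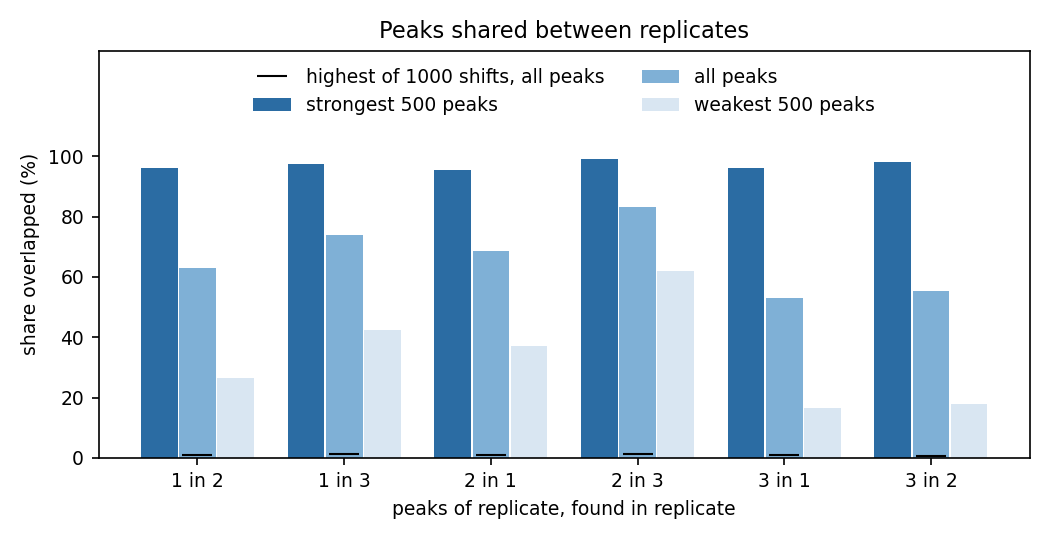
Share of peaks of a replicate (in percent) overlapped by a peak of another, for each of the 6 ordered pairs, with bars for the strongest 500 peaks, all peaks and the weakest 500 peaks, and a line for the highest share in 1000 shifts. Bars for all peaks run from 52.9% to 83.3%, while the shifts stay at or under 1.26%.

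The strongest shared peaks lay mostly at gene starts. The strongest was in an intron at 2L:6612466-6612921, with the nearest start at CG11050 and a signal of 2361. The next was the promoter peak at X:2703719-2704051 of Ugalt, a UDP-galactose transporter, with a signal of 2333, and then that of CG14100 at 3L:19590451-19590782, with a signal of 2135. These held ranks 1 to 3 in each of the 3 replicates, in differing order. Promoter peaks followed at ph-p, a Polycomb group gene, with a signal of 1821, at Chro, which encodes a chromatin protein of interbands, with 1818, and at PNPase, a mitochondrial ribonuclease, with 1682.

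Of the 25 strongest shared peaks, 15 were at promoters, 7 in introns and 3 in intergenic sequence. Promoter peaks also included Tcs5, px, CG7601, CenG1A, CG1888, asRNA:CR45928, tank, lncRNA:CR44339, lncRNA:CR31044 and mRpL23, a mitochondrial ribosomal protein gene, with signals from 1151 to 1457. Intronic ones had their nearest starts at HmgZ, Adf1, CG32772, CG12769, Tlk and CG16753, besides CG11050. Intergenic ones had them at CG13323, lncRNA:CR45643 and lncRNA:CR44761. TGATAC, the core site of Optix and Six3, was within 50 bp of 0 of these 25 summits. Over all conservative-list summits on the main arms its share was 2.86%, so 25 summits are too few to show a difference.

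Promoters were the main location of the listed peaks. In the conservative list 46.9% of summits were at promoters (95% Wilson interval 44.9 to 48.9%), against 14.3% of failing candidates, an odds ratio of 5.30 (4.89 to 5.75). Coding exons held 0.727% of listed summits against 20.6% of failing candidates. Intergenic sequence held 16.0% against 24.4%, and introns held 34.0% against 36.2%. Failing candidates are richer in coding exons than random positions on the main arms, which held 13.1% against 0.734% of listed summits there. Failing candidates also had a higher mean GC content, 48.5% against 38.6%. Over the replicates, promoters held 48.9% ± 2.21 of listed summits (SD, n = 3) and 15.3% ± 1.23 of failing candidates.

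The promoter share was higher than in failing candidates in 3 of 3 replicates, with Fisher's exact tests giving adjusted p = 5.00e-202, 1.39e-214 and 8.53e-269. In the conservative list, adjusted p was 1.78e-210 for coding exons, 1.60e-23 for intergenic sequence, 1.47e-13 for 3' UTRs, 0.0393 for introns and 0.0437 for 5' UTRs, each lower among listed peaks, by the same exact tests. Noncoding exons gave adjusted p = 0.0915 by the exact test. All 7 classes had the same direction in 3 of 3 replicates. The lower share of introns was not called in the longest list (adjusted p = 0.763 by the exact test).

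**Figure D3:**
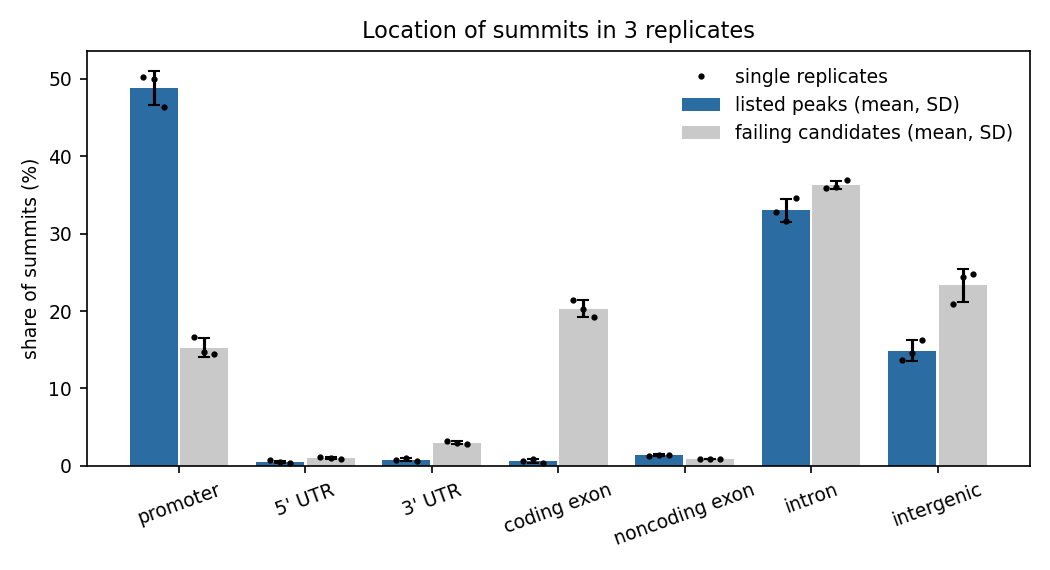
Share of summits (in percent) by location for listed peaks and failing candidates, as means of 3 replicates with SD error bars and a point for each replicate. Promoters hold 48.9% of listed summits against 15.3% of failing candidates, and coding exons hold 0.626% against 20.3%.

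The X chromosome held more of the listed peaks than of the failing candidates, and 3R held fewer. In the conservative list X held 20.9% of peaks against 18.0% (adjusted p = 0.00149 by Fisher's exact test), and was called in 3 of 3 replicates. Arm 3R held 21.6% against 25.5% (odds ratio 0.809, adjusted p = 0.000103 by the exact test), also called in 3 of 3. Arm 2L held 18.7% against 16.8% (odds ratio 1.14, adjusted p = 0.0253 by the exact test), higher in 3 of 3 replicates and called in 0. Arms 2R and 3L were not called. Chromosome 4 had 0 peaks, but only 18 of 129632 failing candidates lay there (0.0139%), so binding there was hardly measured. Replicates 1, 2 and 3 listed 1, 0 and 2 peaks on it. By the same exact test Y (0.0404% against 0.384%, adjusted p = 0.00285) and other contigs (0.969% against 1.81%, adjusted p = 0.00258) were called lower. Over the replicates X held 21.1% ± 0.786 of peaks (SD, n = 3) against 17.1% ± 0.305 of failing candidates. In the longest list X held 19.2% against 18.1% and was not called (adjusted p = 0.162 by the exact test). There 2L (adjusted p = 0.000572) and 3L (20.5% against 18.6%, adjusted p = 0.00802) were called higher by the exact test.

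The Optix core site was not called over all summits. TGATAC was within 50 bp of 70 of 2451 conservative-list summits (2.86%) and of 52 of 2451 matched failing candidates (2.12%), an odds ratio of 1.36 (0.942 to 1.94, adjusted p = 0.317 by Fisher's exact test). The ratio was above 1 in 3 of 3 replicates, at 1.16 ± 0.137 (SD, n = 3), and was called in 0 of them. Outside promoters alone, in a test chosen after seeing the data, it was called, at 3.33% against 1.83% of all failing candidates (odds ratio within GC deciles and location classes 1.43, 1.05 to 1.97, adjusted p = 0.0479 by an exact stratified test), above 1 in 3 of 3 replicates. At promoters it was not (odds ratio 0.889, adjusted p = 0.681 by the exact test). Against matched candidates the longer Optix site GGTATCA had an odds ratio of 1.60 (adjusted p = 0.521 by Fisher's exact test) and was above 1 in 2 of 3 replicates.

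Other sites did differ. TATCGATA, bound by the promoter factor DREF, was at 1.71% of summits against 0.571% (odds ratio 3.03, adjusted p = 0.00346 by Fisher's exact test), was higher in 3 of 3 replicates and was called in 1. The A-tract AAAAAAAA was at 6.73% against 9.30% (odds ratio 0.704, adjusted p = 0.00871 by the exact test), lower in 3 of 3 replicates and called in 2. The other 12 sites, including those of GAGA factor, Zelda, Grainyhead, M1BP and Su(H), were not called in the conservative list against matched candidates. By the same exact test DREF was not called among peaks shared by all 3 replicates (odds ratio 1.38, adjusted p = 1) or at an IDR of at most 0.001 (odds ratio 2.16, adjusted p = 0.528). The A-tract was not called with windows of 100 bp (adjusted p = 0.0597 by the exact test) or against the flanks of the same peaks (odds ratio 1.04), and M1BP was called higher in the longest list (odds ratio 4.62, adjusted p = 0.00475 by the exact test) and against all failing candidates within strata (Mantel-Haenszel odds ratio 3.20). The CA repeat CACACACA, at 48 of 2451 summits against 68 of 2451 matched candidates, was called lower against the flanks (odds ratio 0.458, adjusted p = 4.75e-06 by the exact test) and at an IDR of at most 0.001 (odds ratio 0.230, adjusted p = 0.000963 by the exact test). The tests against flanks treated a peak's flanks as independent of its summit window.

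In the scan of 2080 sequences of 6 bases, 69 were called higher and 47 lower. ACAGTG led, at 10.5% of summits against 4.37% (odds ratio 2.57, adjusted p = 3.99e-13 by Fisher's exact test). ACACTG, which overlaps the M1BP site GGTCACACT in part, followed, at 8.61% against 4.41% (odds ratio 2.04, adjusted p = 2.72e-06 by the exact test). CGATAG, which overlaps the DREF site in part, was at 5.10% against 2.04% (odds ratio 2.58, adjusted p = 5.13e-06 by the exact test). All 3 were higher in 3 of 3 replicates. By location, in a test chosen after seeing the data, CGATAG was called higher at promoters (odds ratio 2.90, adjusted p = 6.93e-18 by the exact stratified test, above 1 in 3 of 3 replicates) and was lower without a call elsewhere (odds ratio 0.765, adjusted p = 0.424 by the same test, above 1 in 1 of 3). The 3 sequences were outside the fixed motifs and are those with the smallest p. ACAGTG and ACACTG share CAGTG, read on either strand, with other called sequences, so the called ones are not all separate sites.

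Of the 21 gene lists, those of ribosomal proteins and of the EGFR pathway were called. Summits lay in or near 19 of 25 ribosomal protein genes (76%), against 16.7% in matched random lists (permutation p = 0.0002, the smallest that 10000 lists can give in a 2-sided test, adjusted p = 0.0042). Among its members, signals were 555 for RpL32, 494 for RpS27, 448 for RpL7 and 268 for RpS20, all in the promoter class. Over the replicates 60% ± 4 of the list had a peak (SD, n = 3), and the list was called in 3 of 3.

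The EGFR pathway, a receptor tyrosine kinase pathway used across the embryo, had summits at 9 of 10 genes (90%), against 36.4% in random lists (permutation p = 0.0008, adjusted p = 0.0084). S, which moves EGFR ligands through the secretory pathway, had a peak with a signal of 657. The transcriptional repressor gene aop had 489, the inhibitor gene aos 444, the ligand gene spi 412, and the effector gene pnt 281. All but the spi peak were in introns. Over the replicates 63.3% ± 5.77 of the list had a peak (SD, n = 3), higher than in random lists in 3 of 3 but called in 0 of 3. By the same permutation test the call was lost with the gene body extended by 10 kb (adjusted p = 0.232), by nearest start (adjusted p = 0.184), at an IDR of at most 0.001 (adjusted p = 0.597) and among peaks shared by all 3 replicates (adjusted p = 0.441).

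**Figure D4:**
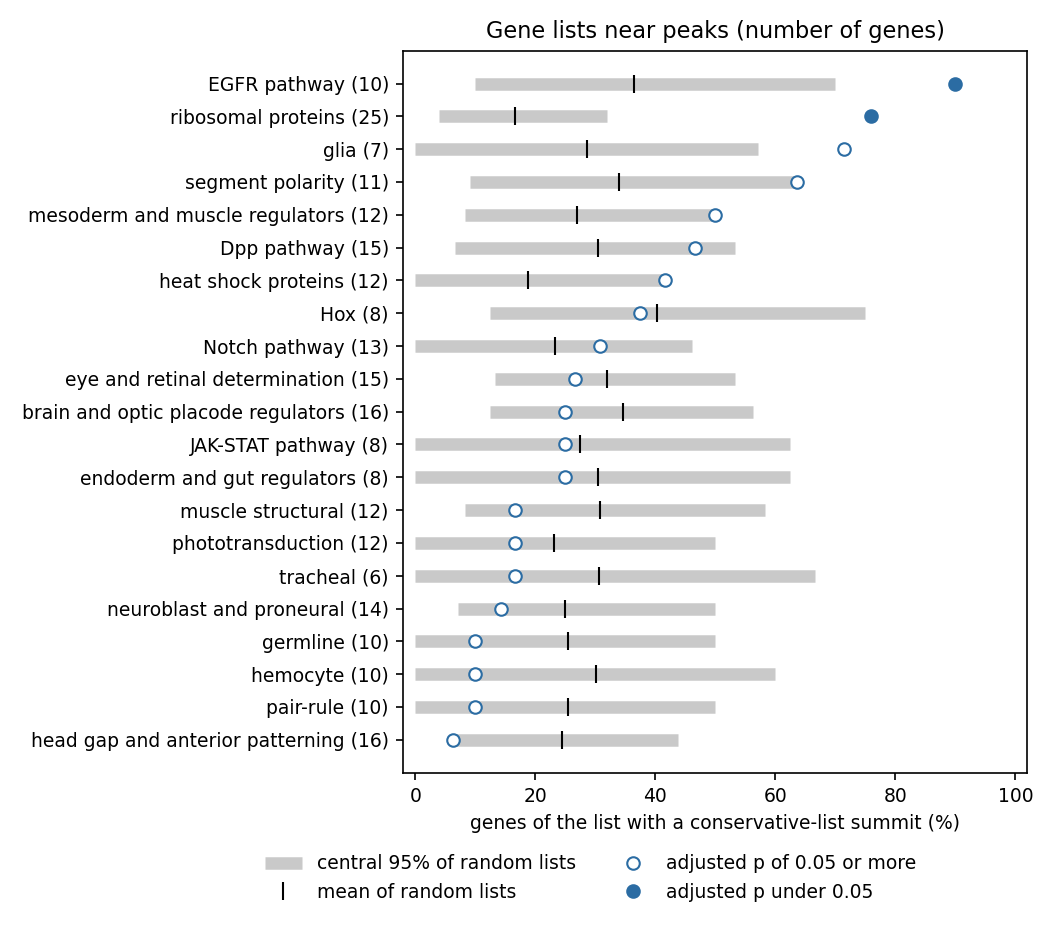
Share of the genes of each fixed list (in percent) with a conservative-list summit in the extended gene body, as points, with the mean and the central 95% of 10000 random lists matched on gene length. The EGFR pathway at 90% and ribosomal proteins at 76% have an adjusted p under 0.05.

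The eye and forebrain lists were not called. Eye and retinal determination genes had peaks at 4 of 15 (26.7%, against 32.0% in random lists), among them the homeodomain gene hth with a signal of 270, and Optix. Those counted without a peak include ey and toy, chosen after their values were seen. Both lie on chromosome 4, where few candidates were found at all. Brain and optic placode regulators had peaks at 4 of 16 (25%, against 34.6%), led by Dr with 299 and tup with 267. The tup peak lies outside tup, 55 bp from the start of another gene, and the Dr peak is intergenic, 10795 bp from the nearest start. Head gap and anterior patterning genes had a peak at 1 of 16, bcd, with a signal of 210. Phototransduction genes had peaks at 2 of 12, norpA with 730 and inaD with 169, and the latter peak is also that of the RpL23 promoter, a gene chosen after its values were seen. In each of these lists the share was lower than in random lists. Adjusted p in these permutation tests ran from 0.441 to 1.

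Signalling and segmentation lists were not called either. Segment polarity genes had peaks at 7 of 11 (63.6%, against 33.9%, adjusted p = 0.396 by permutation, higher in 2 of 3 replicates), led by fz with 446 and nkd with 246. The Dpp pathway had 7 of 15, led by gbb with 1286, whose peak lies at the start of asRNA:CR45928, and Med with 775. The Med peak lies outside Med, 16 bp from the start of another gene. The Notch pathway had 4 of 13, led by E(spl)m8-HLH with 604 and N with 326. The E(spl)m8-HLH peak lies outside that gene, 137 bp from the start of another. The JAK-STAT pathway had 2 of 8, Socs36E with 270 and Stat92E with 205. Hox genes had 3 of 8, led by Antp with 172 and Ubx with 129, and pair-rule genes had 1 of 10, ftz-f1 with 120. Adjusted p in these permutation tests was at least 0.396.

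The tissue and heat shock lists were not called. Glial genes had peaks at 5 of 7 (71.4%, against 28.6%, permutation p = 0.04, adjusted p = 0.28, higher in 3 of 3 replicates), led by moody, a receptor of the blood-brain barrier, with 611, and pnt. Mesoderm and muscle regulators had 6 of 12, led by the muscle regulator Mef2 with 675 and the heart regulator tin with 367. The Mef2 peak lies outside Mef2, 170 bp from the start of another gene. Heat shock proteins had 5 of 12, led by the peak shared by Hsp23 and Hsp27 with 827, and this list was called when passing and failing candidates were compared by Fisher's exact test (odds ratio 5.14, adjusted p = 0.0309). Endoderm and gut regulators had 2 of 8, pnt and bowl. Neuroblast and proneural genes had 2 of 14, grh with 166 and pros with 153, and muscle structural genes had 2 of 12, sls with 345 and Tm2 with 70.5. Tracheal genes had 1 of 6, bnl with 97.6, hemocyte genes 1 of 10, ush with 265, and germline genes 1 of 10, nanos with 144. The nanos peak lies outside nanos, 68 bp from the start of another gene. The bnl peak is intergenic, 2318 bp from the nearest start. Adjusted p in these permutation tests was at least 0.28.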

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

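The tests of GC content, of the share of promoter summits with TGATAC, of failing candidates around Optix and of low-signal peaks were chosen after the result was seen, as was the distance check for divergent promoters.

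Signal was also present in entries outside the listed peaks and outside the main arms. Of the candidates behind the conservative list, 131 passed the IDR limit but were missing from the list, for a reason not given in the sources used here. The strongest, at 2L:480925-481258 in an intron with the nearest start at cbt, had a signal of 2337, which would rank 2 among all that passed, followed by those near Lk6 with 1269 and larp with 1078. These genes were chosen after their values were seen. Of the 131, 25 overlapped candidates left out in the same way in all 3 replicates. Outside the main arms the conservative list held 25 peaks, 24 on X contigs and 1 on Y, which the motif comparison left out, and 0 of these were overlapped in all 3 replicates.

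The promoter excess was weighed against GC content, the Optix core site and divergent promoters. The promoter odds ratio was 5.12 (4.70 to 5.57) within GC deciles, which argues against GC content as the whole source. TGATAC was within 50 bp of 2.33% of listed promoter summits (1.60 to 3.36%), so most of them lacked an exact copy of that site. The low share over all summits, at 70 of 2451, was already known, so this was no separate test. With peaks split by signal into 4 equal groups, TGATAC was at 23 of the 613 strongest and 15 of the 612 weakest (odds ratio 1.55, Fisher's exact p = 0.248), too few to tell whether the site goes with signal. Listed promoter summits lay between divergent starts at most 1 kb apart in 40.7% of cases against 9.39% of failing ones (odds ratio within GC deciles 3.87, 3.37 to 4.44), and within 25-bp bins of distance to the start the ratio was 3.30 (2.81 to 3.88). Divergent promoters may account for part of the excess. Distance was taken without regard to the side of the start, so summits upstream of a start were not told apart from those downstream. The comparison of divergent starts was among promoter summits only, so it does not show how much of the excess would remain without divergent promoters. Forms of the core site other than TGATAC, promoter activity and GFP antibody background stay open, the last as the control experiment named in the labels was not used here.

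The group of peaks around Optix was weighed against extra copies of the tagged locus and binding to the core site. Candidates in coding exons and 3' UTRs within 20 kb, where binding was not expected, had median signals at the 92.5th, 53.7th and 90.9th percentile of such candidates in replicates 1, 2 and 3. Failing candidates of all classes within 20 kb had median signals 1.43, 1.27 and 1.82 times that of the main arms, higher than in all but 10 of 2234, 45 of 2415 and 1 of 2448 windows of that size (lowest percentile 98.1), with 1.31, 1.54 and 1.47 times from 20 to 40 kb away and 1.19, 0.989 and 1.22 times from 40 to 60 kb. Extra copies of the region may raise these signals and with them the number of listed peaks, but broad binding could do so too, and the exon candidates, 10 to 12 in each replicate, did not stand out in replicate 2, so this stays open. TGATAC was at 0 of the 9 listed summits there against 2.87% elsewhere (Fisher's exact p = 1), which 9 peaks cannot decide.

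Low-signal entries were common enough to examine: 117 conservative-list peaks had a signal below the median of failing candidates, 27.6. Of these, 97.4% lay within 350 bp of another entry that passed, against 13.0% of the rest. They may be shoulders of other peaks, and no biological explanation was tested.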

How the results depend on the processing

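The stricter planned limit, an IDR of at most 0.01, equals the authors' own and changed nothing. The limit of 0.001, the restriction to peaks shared by all 3 replicates, the stratified motif tests and the removal of low-signal peaks or of the Optix region were chosen after seeing the data. At an IDR of at most 0.001 the mean replicate count was 1057 in place of 1740, and 608 in place of 919 peaks were in all 3 replicates, since fewer peaks enter. The Spearman correlation of signal ran from 0.759 to 0.864 with each replicate left out. The count of called gene lists fell from 2 to 1 with 10 kb extensions, by nearest start, at an IDR of at most 0.001 and among shared peaks, each time keeping ribosomal proteins, and rose to 3 when passing and failing candidates were compared, which added heat shock proteins (odds ratio 5.14). The cause was not tested. Against the flanks of the same peaks the odds ratio turned to 1.04 for the A-tract and 0.476 for GAGA factor, and to 1.27 for TAATTA. TAATTA also turned to 1.01 with 100 bp windows and 1.04 among shared peaks. GGTATCA turned to 0.896 with 100 bp windows and 0.725 among shared peaks, and was 1 at an IDR of at most 0.001. TGATAC turned to 0.889 at promoters alone. The cause of these turns was not tested, and among them only GAGA factor was called after turning. The promoter excess kept its direction and call under all its alternatives (odds ratio 3.99 to 6.71). The X excess kept them by arm length and at an IDR of at most 0.001 but was not called in the longest list (adjusted p = 0.162 by the exact test). The Optix density was 8.76 to 9.89 times that elsewhere. TGATAC over all locations stayed above 1 without a call, at 1.04 to 1.47. Outside promoters alone TGATAC was called, at 1.43 (adjusted p = 0.0479 by the exact stratified test), for a cause not tested. That call depends on which tests were adjusted together. In all, 126 of 154 alternatives gave the same outcome, those at an IDR of 0.01 by construction, 8 reversed, 8 lost a call, 5 gained one and 7 moved. Besides the heat shock list, which is not counted apart, those that gained one were TGATAC outside promoters, M1BP in the longest list (4.62) and within strata (3.20), and the CA repeat against flanks (0.458) and at an IDR of at most 0.001 (0.230). The same outcome includes results that stayed without a call and values that changed by less than a set limit. Chromosome arms in the longest list were not counted, so the X call lost and the 3L call gained there are left out. Read depth is unknown, so what it limits cannot be given. No pairing of samples between groups was possible because there is 1 group. The comparison with flanks of the same peaks treated flanks and summit windows as independent, so its exact tests ignore that pairing.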

Other observations

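The values below were all chosen after the data were seen. With conservative-list peaks on the main arms split by signal into 4 equal groups, 56.9% of the strongest group were at promoters and 43.5% of the weakest. ACAGTG was at 7.99% of the strongest and 12.3% of the weakest, TATCGATA was at 0.489% and 2.29%, and mean GC content was 34.6% and 43.8%. These differences between groups were not tested. Within GC deciles and location classes, ACAGTG was higher than in failing candidates both at promoters (9.30% against 5.16%, odds ratio 2.01) and elsewhere (11.6% against 4.18%, odds ratio 3.34). TATCGATA had an odds ratio of 4.11 (2.82 to 5.98) at promoters and 1.71 (0.532 to 5.51) elsewhere, where it was above 1 in 0 of 3 replicates. CGATAG had 2.90 at promoters and 0.765 elsewhere. Whether the odds ratios of ACAGTG, TATCGATA, CGATAG or TGATAC differ between locations was not tested.

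Other dense regions of the conservative list, in windows of 40 kb, were X:2280001-2320000 with 9 peaks, which holds Raf, a kinase acting below EGFR, and CG2865, and 3L:2560001-2600000 with 9 peaks, which holds RpL8, dos and msn among other genes. Of these peaks, 6 and 3 were in all 3 replicates.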
